A study of Mus musculus with 9 samples.

How the data were processed

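RNA came from 9 culture dishes of mouse embryonic fibroblasts, 3 dishes for each of 3 cell lines, per the labels. The cells are male, lack both copies of the mouse Ape1 gene and carry a human APE1 transgene, and their Ape1 level is very low, per the labels and the series' design text. How the vector control, human APE1 and mouse Ape1 lines were made is not given in the sources used here. Cells were harvested while growing, in 60 mm dishes in medium with 10% serum, and total RNA was labelled with biotin and read on Affymetrix arrays, per the labels' protocols. Samples were grouped by their titles, which also number the replicates 1 to 3.

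Per the labels, the deposited value of each array is a log2 RMA expression value from Expression Console, in a core-exon analysis. RMA (robust multi-array average) brings the arrays to a common distribution, so a shift of most transcripts at once in 1 group is not measured, and it compresses differences of dim transcripts. The authors also deposited a table of their own 3-group test, whose columns are, per the file headers, group means on the log2 scale, ratios between groups on the linear scale and unadjusted p-values. A shorter deposited table of 7115 transcript clusters holds those whose p-value in the authors' 3-group test passed after adjustment. The authors' group means came from another summary of the arrays than the deposited array values, with r = 0.988 to 0.989 between both, and log2 fold changes correlated at r = 0.971 to 0.975 across transcript clusters. Partek is named without a version in the submitters' processing notes. The array design and the genome build are not given in the sources used here.

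The array values were used as deposited, with no further normalization or filter. All 41345 transcript clusters were tested, including 12100 whose annotation names no gene and 2208 with an empty annotation. Symbols came from the authors' deposited table, where 27 symbols that a spreadsheet had turned into dates or numbers were restored from the full annotation. 1646 symbols stand on more than 1 transcript cluster, and for gene lists and named genes each of 24647 symbols was represented by its brightest cluster, the one with the highest mean over the 9 arrays. 1395 transcript clusters had values identical to those of another on all arrays and were kept. Some clusters, such as those of Alcam in vector control and Dapp1 in mouse Ape1, had the same value on all 3 arrays of a group and were kept too. Chromosomes were taken for 23959 symbols from the files' annotation and a RefSeq gene table of the assembly GRCm38.p6, and no coordinates are given. Apex1 is not analysed here.

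Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes on log2 values, two-sided), in a model of 3 group means over all 9 arrays with 6 residual degrees of freedom and 2.07 added by the prior. The 3 contrasts were human APE1 minus vector control, mouse Ape1 minus vector control and human APE1 minus mouse Ape1, and the moderated F-test compared all 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all transcript clusters within each contrast, and an adjusted p under 0.05 is called a rise or a fall. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 32 lists within each contrast. With an estimated correlation camera called 0 lists in each contrast, against 7, 2 and 6 with the preset one, and limma's fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, called 14, 17 and 14. In either direction, fry called 31, 31 and 30. At an unadjusted p under 0.05, 10070, 11751 and 9774 transcript clusters passed in the 3 contrasts and 13310 in the F-test. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

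The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where a test is said to have been chosen later. The lists were glycolysis, G1 and S phase, G2 and M phase, cyclin-dependent kinase inhibitors, base excision repair, other DNA repair, p53 targets, antioxidant (NRF2) targets, NF-kB and inflammatory genes, interferon-stimulated genes, hypoxia (HIF1) targets, immediate early (AP-1) genes, apoptosis regulators, oxidative phosphorylation, citric acid cycle, cholesterol synthesis, fatty acid synthesis, unfolded protein response, heat shock, ribosomal proteins, fibrillar matrix, matrix proteases, contractile genes, fibroblast markers, Hox genes, and markers of epithelial, endothelial, macrophage, adipocyte, skeletal muscle, cartilage and bone, and neural and glial cells. Xist and 4 Y-linked genes are given as values. Named genes were Apex2, and in each contrast the 10 genes with the largest rise and the 10 with the largest fall among those that passed and whose 3 values in one group all lay above the 3 in the other. Symbols of predicted or non-coding genes and of large families of near-identical copies (such as olfactory receptors and histones) were left out of these. To them come, in each list and contrast, up to 2 members that rose and up to 2 that fell with the smallest adjusted p, and 6 genes each that moved the same way and in opposite ways in both lines, ranked by the smaller of their 2 changes. The text names fewer of these, in the order of the rule, skipping some whose call rested on 1 array or on the chromosome medians, and some others are not reported here.

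Because both comparisons against vector control use the same arrays, their similarity was set beside 100 simulations of unchanged groups against those arrays. The fit was tested on simulated data made from the human APE1 against vector control comparison, with 50 of 41345 transcript clusters changed at each size. It recovered 2% of changes of 1.2-fold, 48% of 1.5-fold, 76% of 2-fold and 92% of 4-fold, and 4.39% of its calls were false. The real comparison of human APE1 against vector control called 4859, which makes the adjusted threshold less strict, so recovery there may differ. A simulated covariance of 0.0247 between both effects was recovered as 0.0247. The subtraction used the same spread that made the data, so this checks the calculation only. The median SD within groups was 0.120 in vector control, 0.116 in human APE1 and 0.101 in mouse Ape1, on the log2 scale, and the number of arrays limits the precision. Alternatives were quantile normalization run again, array medians subtracted, dim clusters under the 25th percentile left out, only clusters with a symbol, no moderation of the variance, a variance trend with robust estimation, only both groups of a contrast, array weights, the replicate number as a block, an adjusted p under 0.01, a change of at least 1.5-fold, the p-values of the authors' deposited table, other gene list tests, and each array left out in turn. Subtraction of the median of each chromosome was added after the data were seen.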

Results

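Gene expression was measured on 9 arrays, 1 for each culture dish of mouse embryonic fibroblasts (MEFs), connective tissue cells taken from the mouse embryo. The labels and the series' design text describe cells with very little Ape1, a level that was not checked here in any of the 3 groups. Ape1 is the apurinic/apyrimidinic endonuclease that cuts DNA at positions that have lost their base, a step of base excision repair. It also acts as a redox regulator of transcription factors. Per the same sources, the cells lack both copies of the mouse Ape1 gene and carry a human APE1 transgene. Vector control can therefore not be taken as free of human APE1. The 9 arrays fell into 3 groups of 3, named vector control, human APE1 and mouse Ape1 in the labels. The series asked how clusters of genes, among them those of glycolysis and of the cell cycle, are regulated by the human and by the mouse protein. Each array gave log2 expression values for 41345 transcript clusters, of which 27037 (65.4%) carried a symbol, 24647 genes in all. Array medians lay between 5.64 and 5.75. Across transcript clusters, which are not independent replicates, arrays of the same group correlated at r = 0.990 to 0.993 (9 pairs) and arrays of different groups at r = 0.977 to 0.987 (27 pairs). Each group was 1 cell line, so the p-values measure only the spread between dishes of 1 line, and group and line cannot be told apart. The number of arrays limits the precision, and the median SE of a difference between groups was 0.106 on the log2 scale. Apex1, the mouse gene for Ape1, is not analysed here, so the group labels were not checked against it. Its relative Apex2 did not pass the test against vector control in the human APE1 line (log2 difference −0.27, adjusted p = 0.151) or the mouse Ape1 line (0.18, adjusted p = 0.301).

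With all 3 groups in 1 test, 8455 of 41345 transcript clusters (20.4%) differed at an adjusted p under 0.05. In the 3 comparisons between groups, 120, 118 and 129 results for single genes that were chosen by the rule for named genes passed the test, and in each of them all 3 arrays of one group lay above all 3 of the other, as the rule itself required for the largest changes. Medians of the expressed genes of single chromosomes differed between the lines too, by 0.36 for chromosome 12 in mouse Ape1 against vector control. Values in brackets after a gene are differences of group means on the log2 scale, the first-named group minus the second.

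The first comparison asked how expression in the human APE1 line differs from that in vector control. In the human APE1 line 19 of 30 extracellular matrix genes and 8 of 18 contractile genes fell, and 10 of 32 genes of the G2 and M phases rose. These lists passed limma's camera test with a preset correlation, and had adjusted p = 0.0567, 0.389 and 0.463 with an estimated correlation. Acta2, smooth muscle actin, fell 13.6-fold, by 3.77 on the log2 scale (8.18 ± 0.18 against 11.95 ± 0.027, SD, n = 3 each, SE of the difference 0.11, adjusted p = 1.45e-06), and Tagln, the actin-binding protein transgelin, fell by 2.19. In the authors' deposited table, the ratio of vector control over human APE1 for Acta2 was 9.96 (p = 1.51e-07). Slit2, a secreted guidance ligand, fell by 3.90 (SE 0.06, adjusted p = 4.02e-08), and Emb, embigin, a partner of monocarboxylate transporters, fell 18.4-fold (−4.20).

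Of 41345 transcript clusters, 4859 (11.8%) passed the test, of which 2233 rose and 2626 fell (46.0% rose), and 229 rose and 365 fell by at least 2-fold. The count was 3185 without human APE1 replicate 1 and 3203 without human APE1 replicate 2. The share that rose was 35.9% after array medians were subtracted and 63.3% after chromosome medians were subtracted, so the balance of rises and falls depended on the scaling. At the level of genes, 3872 of 24647 passed, of which 1621 rose and 2251 fell, 96 and 303 of them by at least 2-fold. The values of both groups did not overlap in 26.7% of transcript clusters, where chance gives 10%.

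Among the single genes with large falls was Rbmy1a1, a Y-encoded RNA-binding protein of germ cells (−6.68, adjusted p = 4.35e-08), which stands on 9 transcript clusters of a multicopy family and is uncertain as to which copy was measured. So were Pcdh7, a protocadherin (−4.65), Emb, Slit2 and Igfbp7, a secreted protein that binds insulin-like growth factors (−3.84). Others were Col12a1, a fibril-associated collagen (−3.49), Dapp1, an adaptor of phosphoinositide signalling (−3.41), Slc6a15, an amino acid transporter (−3.30), and B4galt6, a glycolipid galactosyltransferase (−3.19). In the human APE1 line the means of Rbmy1a1 (3.50), Pcdh7 (3.94) and Dapp1 (4.09) lay below the 25th percentile of the arrays (4.29 to 4.36), where RMA compresses differences, so the size and rank of these falls are uncertain. Rex2 rose by 2.73 (5.89 ± 0.25 against 3.16 ± 0.25, SD, n = 3 each, SE of the difference 0.20, adjusted p = 0.000126), Renbp, the renin-binding protein, by 1.99 (adjusted p = 2.76e-05), Slc5a7, a choline transporter, by 1.87, Klhl28 by 1.86 and Ptn, the growth factor pleiotrophin, by 1.85 (adjusted p = 9.01e-05). Arl6ip1 (1.84) and the adhesion molecule Mcam (1.83, adjusted p = 3.98e-06) rose as well. The mean of Rex2 in vector control lay below the 25th percentile too (4.27 to 4.32), so the size of its rise is uncertain.

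Among 30 genes of the fibrillar extracellular matrix, 1 rose and 19 fell (1 and 19 adjusted over the list alone), with a median difference of −0.46. The list as a whole stood lower than other genes in limma's camera test (adjusted p = 3.5e-11), and adjusted p = 0.0567 with an estimated correlation. Col12a1 and Dcn, the proteoglycan decorin (−3.06), fell and Col5a2, a fibrillar collagen chain (0.74), rose. Fibroblast markers went the same way, with 0 of 17 higher and 7 lower (1 and 7 adjusted over the list alone), Dcn and Col1a1 (−0.94) among them, both also on the matrix list (camera adjusted p = 0.000529, and adjusted p = 0.166 with an estimated correlation). Of 18 contractile genes, 1 rose and 8 fell (2 and 9 adjusted over the list alone, median −0.23), led by Acta2 and Tagln (camera adjusted p = 0.00238, and adjusted p = 0.389 with an estimated correlation). Of 20 matrix proteases and their inhibitors, 2 rose and 6 fell (2 and 7 adjusted over the list alone), among them Timp3, an inhibitor of metalloproteinases (0.97), and Ctsl, the lysosomal protease cathepsin L (−1.56). That list's camera result was weak (adjusted p = 0.0454, and adjusted p = 0.463 with an estimated correlation). It was lost without vector control replicate 2 (0.0538) or 3 (0.0848), human APE1 replicate 2 (0.0959), and mouse Ape1 replicate 1 (0.0515) or 3 (0.0533), and when dim genes were left out of the background (0.102).

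Of 32 genes of the G2 and M phases of the cell cycle, 10 rose and 0 fell (13 and 1 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.00238, and adjusted p = 0.463 with an estimated correlation). Cenpf, a kinetochore protein (0.50), and Bub1b, a spindle checkpoint kinase (0.45), were among those that rose. Of 32 genes of the G1 and S phases, 6 rose and 7 fell (9 and 8 adjusted over the list alone), and the list did not pass as a whole (adjusted p = 0.948). Within it Ccnd2, cyclin D2, fell by 2.26 (SE 0.06, adjusted p = 7.17e-07), while the kinases Cdk4 (0.52) and Cdk2 (0.46) rose. Of 23 glycolysis genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), and the list did not pass either (adjusted p = 0.948). Pdk1, a kinase that keeps pyruvate from the mitochondrial pathway (0.62), and Ldhb, a lactate dehydrogenase subunit (0.56), rose.

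Of 20 genes of the unfolded protein response, 2 rose and 7 fell (2 and 11 adjusted over the list alone, median −0.18), with camera adjusted p = 0.00238, and adjusted p = 0.588 with an estimated correlation. Sel1l, a part of the degradation machinery of the endoplasmic reticulum (−1.06), and Sdf2l1 (−0.83) fell, while Ddit3, the stress transcription factor CHOP (0.48), rose. Of 29 interferon-stimulated genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone, median −0.19), with camera adjusted p = 0.00441, and adjusted p = 0.205 with an estimated correlation. Isg15, a ubiquitin-like modifier (−1.25), and Ifih1, a sensor of double-stranded RNA (−1.08), fell, and Stat2, a transcription factor of the interferon response (0.76), rose. Of 25 NF-kB and inflammatory genes, 2 rose and 5 fell (2 and 5 adjusted over the list alone, adjusted p = 0.189), with the chemokines Ccl5 (−1.51) and Cxcl10 (−1.12) lower. Of 24 p53 targets, 7 rose and 3 fell (7 and 5 adjusted over the list alone, adjusted p = 0.318), with Plk2 (0.67) and Mdm2, the ubiquitin ligase of p53 (0.65), higher and the death receptor Fas (−1.30) lower. Of 24 cholesterol synthesis genes, 7 rose and 2 fell (9 and 3 adjusted over the list alone, adjusted p = 0.166). The 4 Y-linked genes chosen beforehand fell, Ddx3y (−1.15), Eif2s3y (−0.75), Kdm5d (−1.05) and Uty (−0.96), while Xist, the RNA of the silenced X chromosome, differed by −0.12 (adjusted p = 0.789).

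**Figure D1:**
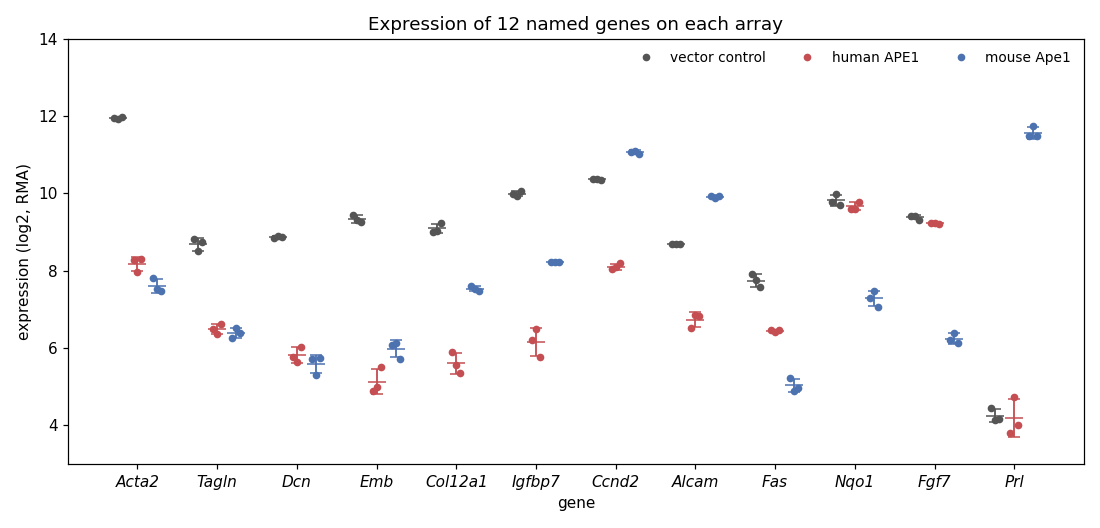
Log2 expression of 12 genes chosen by the rule for named genes, in vector control, human APE1 and mouse Ape1 (dots, single arrays; bars, mean ± SD, n = 3 each). Acta2 lay at 11.95 ± 0.027 in vector control, 8.18 ± 0.18 in the human APE1 line and 7.60 ± 0.17 in the mouse Ape1 line, and Prl was high in the mouse Ape1 line only, at 11.57 ± 0.15, among the 3 groups.

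The second comparison asked how expression in the mouse Ape1 line differs from that in vector control. Prl, the hormone prolactin, was higher in the mouse Ape1 line by 7.32 on the log2 scale (11.57 ± 0.15 against 4.25 ± 0.16, SD, n = 3 each, SE of the difference 0.22, adjusted p = 1.28e-06). Its mean in vector control lay below the 25th percentile of those arrays (4.27 to 4.32), where RMA compresses differences, so no fold is given. Acta2 was 20.4-fold lower (7.60 ± 0.17 against 11.95 ± 0.027, SD, n = 3 each, SE of the difference 0.11, adjusted p = 6.02e-07) and Tagln fell by 2.31. In the mouse Ape1 line 10 of 25 inflammatory and 11 of 29 interferon-stimulated genes fell, and the lists passed camera with a preset correlation but had adjusted p = 0.142 and 0.244 with an estimated correlation. The cyclins D1 and D2 and the glucose transporter Slc2a1 were higher. In the authors' deposited table, the ratio of vector control over mouse Ape1 was 15.8 for Acta2 (p = 5.09e-08) and 0.00750 for Prl (p = 9.98e-09). The ratio for Prl rests on the same dim group, so its size is uncertain.

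Of 41345 transcript clusters, 6681 (16.2%) passed the test, of which 3758 rose and 2923 fell (56.2% rose), and 622 rose and 285 fell by at least 2-fold. Without mouse Ape1 replicate 1 the count was 4433. The share that rose was 44.5% after array medians were subtracted. Of 24647 genes, 4917 passed, 2404 with a rise and 2513 with a fall, and by at least 2-fold 222 genes rose and 250 fell, a balance opposite to that of the transcript clusters. The values of both groups did not overlap in 33.1% of transcript clusters, where chance gives 10%.

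Among the largest rises after Prl were Aldh1a1, a retinaldehyde dehydrogenase (3.51, adjusted p = 1.68e-05), Zdhhc15, a palmitoyltransferase (3.38), Ptprq, a receptor phosphatase (3.28, adjusted p = 1.19e-06), Htra1, a secreted serine protease (3.27), Slc35f2 (3.14) and Igsf11, an adhesion molecule (3.02). Among the largest falls were Rbmy1a1 (−6.54, adjusted p = 6.03e-08), Acta2, Emb (−3.35), Dcn (−3.29), Anpep, an aminopeptidase of the cell surface (−3.19), and Fgf7, a growth factor for epithelial cells (−3.14, adjusted p = 3.55e-07). Zdhhc15 in vector control (3.51) and Rbmy1a1 in the mouse Ape1 line (3.64) also lay below the 25th percentile of their arrays (4.27 to 4.32 and 4.32 to 4.34), so the size and rank of these differences are uncertain.

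Of 25 NF-kB and inflammatory genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone, median −0.20), with camera adjusted p = 0.00226, and adjusted p = 0.142 with an estimated correlation. The chemokines Ccl5 (−1.52) and Ccl2 (−1.94) fell. Of 29 interferon-stimulated genes, 0 rose and 11 fell (0 and 13 adjusted over the list alone, median −0.25), with camera adjusted p = 0.00653, and adjusted p = 0.244 with an estimated correlation. Bst2, tetherin (−0.85), and Gbp2, a guanylate-binding protein (−1.09), fell. The other lists did not pass as wholes in this comparison. Of 30 matrix genes, 6 rose and 14 fell (7 and 14 adjusted over the list alone, adjusted p = 0.0776), Thbs1, a thrombospondin (0.90), with a rise and its relative Thbs2 (−2.67) and the collagen cross-linking enzyme Lox (−2.70) with falls. Of 18 contractile genes, 3 rose and 7 fell (4 and 8 adjusted over the list alone, adjusted p = 0.0776), with smoothelin, Smtn (0.60), and filamin, Flna (0.54), higher beside the lower Acta2 and Tagln. Without vector control replicate 2 both lists passed (adjusted p = 0.0481 each), while with an estimated correlation on all arrays both had adjusted p = 0.707. Of 17 fibroblast markers, 3 rose and 7 fell (3 and 7 adjusted over the list alone, adjusted p = 0.0776), Prrx1, a transcription factor of mesenchyme (−1.86), among the latter. Of 20 matrix proteases and inhibitors, 2 rose and 4 fell (3 and 4 adjusted over the list alone, adjusted p = 0.593), with the aggrecan-cleaving protease Adamts5 (1.25) higher and Ctsl (−1.18) lower.

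Of 23 glycolysis genes, 5 rose and 3 fell (6 and 5 adjusted over the list alone, adjusted p = 0.534), a balance that became 4 and 5 after quantile normalization was run again. Slc2a1 (0.70, adjusted p = 0.000107) and Pgk1, phosphoglycerate kinase (0.48), rose, and Eno2, an enolase (−0.29), fell. Of 32 G1 and S phase genes, 10 rose and 3 fell (12 and 5 adjusted over the list alone, adjusted p = 0.0776), with Ccnd1 (0.74) and Ccnd2 (0.70) higher. Of 32 G2 and M phase genes, 2 rose and 11 fell (4 and 12 adjusted over the list alone, adjusted p = 0.0776), with Hmmr, a spindle protein (−0.51), and Mad2l1, a checkpoint protein (−0.34), lower. Of 24 p53 targets, 4 rose and 7 fell (5 and 7 adjusted over the list alone, adjusted p = 0.650), with Sesn2 (1.03) higher and Fas (−2.71, adjusted p = 5.1e-06) lower. Of 20 genes of the unfolded protein response, 7 rose and 4 fell (8 and 5 adjusted over the list alone, adjusted p = 0.534), with Chac1 (1.01) higher and Sel1l (−1.02) lower. Of 24 cholesterol synthesis genes, 3 rose and 8 fell (5 and 10 adjusted over the list alone, adjusted p = 0.141), with Dhcr7, a late enzyme of the pathway (−0.52), lower. Among Y-linked genes, Ddx3y (0.42) and Kdm5d (0.43) rose, while Eif2s3y differed by 0.23 (adjusted p = 0.0656) and Xist by −0.18 (adjusted p = 0.648). Uty differed by 0.30 (adjusted p = 0.0335), a call lost without any 1 of the vector control or mouse Ape1 arrays or human APE1 replicate 2 (adjusted p = 0.0536 to 0.110).

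The third comparison set the human APE1 line against the mouse Ape1 line, to find where the 2 lines differ, whatever the cause. Prl was lower in the human APE1 line, with a difference of −7.38 on the log2 scale (4.19 ± 0.49 against 11.57 ± 0.15, SD, n = 3 each, SE of the difference 0.22, adjusted p = 2e-06), and cyclin D2, Ccnd2, differed by −2.96 (SE 0.06, adjusted p = 5.22e-07). Nqo1, a quinone reductase of the antioxidant response, was higher in the human APE1 line (2.38, adjusted p = 1.99e-05), as were 16 of 32 genes of the G2 and M phases and 8 of 24 cholesterol synthesis genes. Of 20 genes of the unfolded protein response, 10 were lower there. These 3 lists passed camera with a preset correlation, and had adjusted p = 0.455, 0.601 and 0.601 with an estimated correlation.

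Of 41345 transcript clusters, 5130 (12.4%) passed the test, 2028 of them higher and 3102 lower in the human APE1 line (39.5% higher), and 112 were higher and 532 lower by at least 2-fold. The share that was higher became 57.6% after chromosome medians were subtracted. Of 24647 genes, 4081 passed, 1767 higher and 2314 lower, 88 and 285 of them by at least 2-fold. The values of both groups did not overlap in 28.7% of transcript clusters, where chance gives 10%.

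Higher in the human APE1 line were Fgf7 (2.99, adjusted p = 1.05e-06), Nqo1, Slc5a7 (2.25), Rex2 (2.21), Ablim1, an actin-binding protein (2.05), Reep6 (1.98) and Pdk4, a pyruvate dehydrogenase kinase (1.96). Lower, after Prl, were Aldh1a1 (−3.95), Asap2 (−3.76), Ptprq (−3.69), Pcdh7 (−3.65), Tll1, a tolloid-like metalloprotease (−3.51, adjusted p = 1.91e-07), Slc35f2 (−3.41) and Zdhhc15 (−3.41). The means of Prl, Pcdh7 and Zdhhc15 in the human APE1 line and of Rex2 in the mouse Ape1 line lay below the 25th percentile of their arrays, which leaves the size and rank of these differences uncertain.

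Of 32 G2 and M phase genes, 16 were higher and 2 lower in the human APE1 line (23 and 2 adjusted over the list alone, median 0.21), with camera adjusted p = 1.41e-06, and adjusted p = 0.455 with an estimated correlation. Cenpf (0.81, adjusted p = 9.66e-05) and Kif11, a spindle motor (0.65), were higher. Of 24 cholesterol synthesis genes, 8 were higher and 2 lower (12 and 2 adjusted over the list alone, median 0.21), with camera adjusted p = 0.00509, and adjusted p = 0.601 with an estimated correlation. Hmgcs1, an early enzyme of the pathway (0.90), and Srebf2, its transcription factor (0.56), were higher. Of 20 genes of the unfolded protein response, 2 were higher and 10 lower (2 and 12 adjusted over the list alone, median −0.20), with camera adjusted p = 2.46e-05, and adjusted p = 0.601 with an estimated correlation. Herpud1, a protein of endoplasmic reticulum degradation (−0.94), and Chac1, an enzyme that breaks down glutathione (−0.88), were lower. Of 25 NF-kB and inflammatory genes, 6 were higher and 0 lower (7 and 1 adjusted over the list alone), with camera adjusted p = 0.0385, and adjusted p = 0.455 with an estimated correlation. Nfkbia, the inhibitor of NF-kB (1.05), and Ccl2 (1.62) were higher, and the call was lost without human APE1 replicate 2 (adjusted p = 0.0808) or 3 (0.0551). Of 24 p53 targets, 10 were higher and 2 lower (10 and 2 adjusted over the list alone), with camera adjusted p = 0.0385, and adjusted p = 0.601 with an estimated correlation. Fas (1.42) and Polk, a translesion polymerase (0.53), were higher and Sesn2 (−0.66) was lower. The call was lost without vector control replicate 1 (adjusted p = 0.0560), without human APE1 replicate 2 (0.0619) or 3 (0.121), and after chromosome medians were subtracted (0.243). Of 30 matrix genes, 5 were higher and 12 lower (6 and 13 adjusted over the list alone, median −0.15), with camera adjusted p = 0.0385, and adjusted p = 0.601 with an estimated correlation. Fbn1, fibrillin (1.67), was higher and Col1a2 (−1.20) and tenascin, Tnc (−1.54), were lower, and the call was lost without human APE1 replicate 2 (adjusted p = 0.0827). The calls for NF-kB genes and p53 targets (adjusted p = 0.0774 each) and for matrix genes (0.0925) were lost as well when dim genes were left out of the background.

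Neither glycolysis (3 higher and 5 lower of 23, 6 and 7 adjusted over the list alone, adjusted p = 0.671) nor the G1 and S phase list (3 and 6 of 32, 5 and 10 adjusted over the list alone, adjusted p = 0.106) passed as a list between the human APE1 and mouse Ape1 lines. Their members did differ, with Slc2a1 (−0.56) and Ccnd1 (−0.70) lower and Pdk1 (0.51) and Rbl1, a pocket protein that holds back E2F (0.44), higher in the human APE1 line. Pgk1 was lower there too (−0.63), a difference of −0.16 (adjusted p = 0.0970) after chromosome medians were subtracted. Of 29 interferon-stimulated genes, 5 were higher and 2 lower (9 and 3 adjusted over the list alone, adjusted p = 0.467), of 20 matrix proteases and inhibitors 3 and 6 (3 and 7 adjusted over the list alone, adjusted p = 0.331), of 18 contractile genes 4 and 5 (5 and 5 adjusted over the list alone, adjusted p = 0.740), and of 17 fibroblast markers 2 and 5 (2 and 6 adjusted over the list alone, adjusted p = 0.398). Ifih1 (−1.34) was lower and Timp3 (0.97) and Prrx1 (1.76) were higher in the human APE1 line. All 4 Y-linked genes were lower there, Ddx3y (−1.57), Eif2s3y (−0.98), Kdm5d (−1.48) and Uty (−1.25), and Xist differed by 0.05 (adjusted p = 0.920). Apex2 differed by −0.45 (adjusted p = 0.0241), a difference that became 0.02 (adjusted p = 0.928) after chromosome medians were subtracted and that was lost without human APE1 replicate 1 (adjusted p = 0.0823) or 3 (0.0757) or mouse Ape1 replicate 1 (0.0669) or 2 (0.0562).

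**Figure D2:**
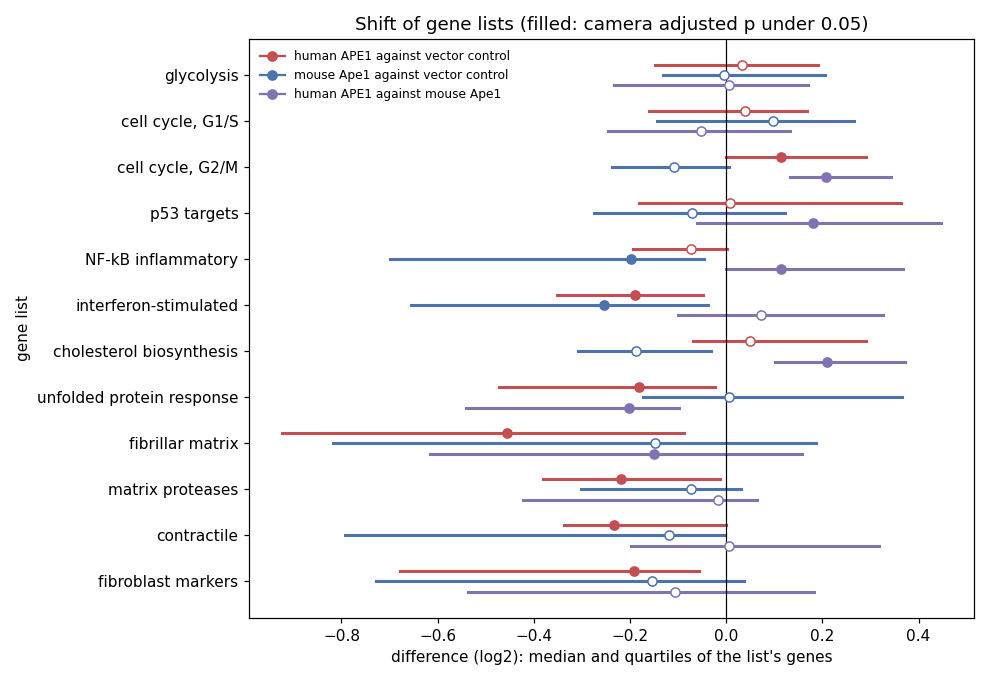
Shift of 12 of the gene lists, as the median log2 difference of the members of each list in the 3 comparisons, with lines from the lower to the upper quartile and filled symbols where the camera test passed at an adjusted p under 0.05. The matrix list has a median of −0.46 in human APE1 against vector control, and the G2 and M phase list a median of 0.11 in that comparison and 0.21 in human APE1 against mouse Ape1.

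The remaining lists did not pass the camera test in any comparison, and their adjusted p-values are given in the order human APE1 against vector control, mouse Ape1 against vector control, and human APE1 against mouse Ape1. Of 23 base excision repair genes, 4 rose and 3 fell in the human APE1 line (4 and 5 adjusted over the list alone) and 2 rose and 4 fell in the mouse Ape1 line (3 and 4). Between the lines, 2 were higher and 2 lower (3 and 4). The ligase Lig3 fell in both lines (−0.34 and −0.37) and the repair polymerase Polb rose in the mouse Ape1 line (0.48), while the list had adjusted p = 0.579, 0.645 and 0.942. Of 30 genes of other DNA repair pathways, 7 rose and 1 fell in the human APE1 line (9 and 1 adjusted over the list alone) and 9 rose and 4 fell in the mouse Ape1 line (11 and 4). Between the lines, 7 were higher and 4 lower (7 and 6), with adjusted p = 0.189, 0.185 and 0.942. Rad50, of the complex that binds broken ends, rose by 0.43 in the human APE1 line, and the checkpoint kinase Chek1 rose by 0.42 in the mouse Ape1 line, where Fancd2 fell by 0.40. Of 7 cyclin-dependent kinase inhibitors, 1 rose and 1 fell in the human APE1 line (2 and 1 adjusted over the list alone) and 0 rose and 0 fell in the mouse Ape1 line (0 and 0). Between the lines, 2 were higher and 1 lower (3 and 1), with adjusted p = 0.294, 0.886 and 0.331. Cdkn2c rose by 0.35 in the human APE1 line, where Cdkn2b was higher by 0.52 than in the mouse Ape1 line. Of 24 apoptosis regulators, 2 rose and 6 fell in the human APE1 line (6 and 6 adjusted over the list alone) and 2 rose and 9 fell in the mouse Ape1 line (4 and 10). Between the lines, 6 were higher and 3 lower (8 and 3), with adjusted p = 0.896, 0.291 and 0.186.

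Among 28 antioxidant (NRF2) targets, 3 rose and 6 fell in the human APE1 line (3 and 8 adjusted over the list alone) and 2 rose and 8 fell in the mouse Ape1 line (2 and 8). Between the lines, 5 were higher and 5 lower (9 and 6), with adjusted p = 0.30, 0.141 and 0.589. Nqo1 fell by 2.54 in the mouse Ape1 line (SE 0.12, adjusted p = 1.03e-05). The cystine transporter Slc7a11 fell (−1.66 and −1.30) and the carbonyl reductase Cbr1 rose (0.47 and 0.61) in both lines. Among 24 immediate early (AP-1) genes, 1 rose and 4 fell in the human APE1 line (1 and 4 adjusted over the list alone) and 3 rose and 9 fell in the mouse Ape1 line (3 and 9). Between the lines, 5 were higher and 3 lower (5 and 3), with adjusted p = 0.275, 0.501 and 0.972. Ctgf, connective tissue growth factor, fell in both lines (−0.94 and −0.97). Among 23 hypoxia (HIF1) targets, 4 rose and 4 fell in the human APE1 line (5 and 6 adjusted over the list alone) and 4 rose and 3 fell in the mouse Ape1 line (4 and 4). Between the lines, 4 were higher and 3 lower (7 and 6), with adjusted p = 0.995, 0.665 and 0.890. Among 15 heat shock genes, 1 rose and 2 fell in the human APE1 line (2 and 4 adjusted over the list alone) and 2 rose and 3 fell in the mouse Ape1 line (2 and 3). Between the lines, 2 were higher and 2 lower (2 and 2), with adjusted p = 0.896, 0.846 and 0.972.

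Of 22 citric acid cycle genes, 3 rose and 6 fell in the human APE1 line (3 and 9 adjusted over the list alone) and 5 rose and 3 fell in the mouse Ape1 line (7 and 7). Between the lines, 4 were higher and 6 lower (6 and 6), with adjusted p = 0.275, 0.665 and 0.422. Ogdh, a subunit of the oxoglutarate dehydrogenase complex, rose by 0.47 in the human APE1 line, and fumarate hydratase, Fh1, fell by 0.65 in the mouse Ape1 line. Of 29 oxidative phosphorylation genes, 2 rose and 2 fell in the human APE1 line (2 and 2 adjusted over the list alone) and 5 rose and 3 fell in the mouse Ape1 line (6 and 5). Between the lines, 2 were higher and 4 lower (5 and 6), with adjusted p = 0.406, 0.593 and 0.422. Of 15 fatty acid synthesis genes, 1 rose and 2 fell in the human APE1 line (1 and 5 adjusted over the list alone) and 2 rose and 5 fell in the mouse Ape1 line (3 and 5). Between the lines, 3 were higher and 3 lower (5 and 3), with adjusted p = 0.178, 0.291 and 0.890. Single ribosomal protein genes out of 25 passed in each comparison, 1 with a rise in each line and 1 lower in human APE1 than in mouse Ape1, and 0 did so adjusted over the list alone (adjusted p of the list = 0.933, 0.886 and 0.740). Of 31 Hox genes, which set position along the body axis, 5 rose and 4 fell in the human APE1 line (6 and 5 adjusted over the list alone) and 1 rose and 7 fell in the mouse Ape1 line (2 and 8). Between the lines, 8 were higher and 2 lower (10 and 4), with adjusted p = 0.948, 0.622 and 0.444. Hoxc8 fell in both lines (−0.78 and −1.52) and Hoxd8 rose in the mouse Ape1 line (0.73).

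On the 7 lists of markers of other cell types, 92 markers were measured, of which 2 (2.17%) rose and 9 fell in the human APE1 line against vector control, and 3 (3.26%) rose and 2 fell in the mouse Ape1 line. In the human APE1 line 1 endothelial marker and 1 adipocyte marker rose, while 3 neural and glial, 2 cartilage and bone, 2 adipocyte, 1 macrophage and 1 skeletal muscle marker fell. Spp1, the matrix protein osteopontin (−2.37), the neural adhesion molecule Ncam1 (−0.91) and the neuronal tubulin Tubb3 (−1.69) were among the latter. In the mouse Ape1 line 1 endothelial, 1 cartilage and bone and 1 neural or glial marker rose, and 1 macrophage and 1 adipocyte marker fell. Between the human APE1 and mouse Ape1 lines, 2 adipocyte, 1 endothelial and 1 cartilage and bone marker were higher and 3 neural and glial, 3 cartilage and bone, 1 endothelial, 1 adipocyte and 1 skeletal muscle marker lower. None of 14 epithelial markers passed in limma's test in any comparison. Adjusted over the list alone, the counts were the same except that 2 endothelial markers were lower between the lines and no neural or glial marker rose in the mouse Ape1 line. The lists had adjusted p = 0.995, 0.665 and 0.740 for epithelial, 0.995, 0.593 and 0.669 for endothelial, 0.948, 0.623 and 0.444 for macrophage and 0.947, 0.501 and 0.444 for adipocyte markers. They had adjusted p = 0.995, 0.978 and 0.942 for skeletal muscle, 0.381, 0.846 and 0.453 for cartilage and bone, and 0.166, 0.665 and 0.331 for neural and glial markers.

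A list's median, its mean and the direction of its test differed in sign for G1 and S phase genes, hypoxia targets, heat shock, endothelial markers, macrophage markers, adipocyte markers and Hox genes in human APE1 against vector control, for glycolysis, hypoxia targets, the citric acid cycle, heat shock and ribosomal proteins in mouse Ape1 against vector control, and for glycolysis, base excision repair, hypoxia targets, immediate early genes, fatty acid synthesis, heat shock, ribosomal proteins, contractile genes, skeletal muscle markers, cartilage and bone markers and neural and glial markers in human APE1 against mouse Ape1, none of which passed. The 15 results of lists that passed kept the sign of their median and the balance of rises and falls after quantile normalization was run again, after array medians were subtracted and after chromosome medians were subtracted.

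Both effects against vector control were then set against each other, since the series asked how genes are regulated by the human and by the mouse protein. The smooth muscle actin gene Acta2 (−3.77 in the human APE1 line and −4.35 in the mouse Ape1 line), Emb (−4.20 and −3.35), Dcn (−3.06 and −3.29) and the cadherin Cdh11 (−2.96 and −2.68) fell in both. Between the lines, Acta2 was higher by 0.58 in the human APE1 line (adjusted p = 0.0116) and Emb was lower, with a difference of −0.85 (adjusted p = 0.0148), the latter lost without human APE1 replicate 1 (0.0517) or 2 (0.0572) or mouse Ape1 replicate 1 (0.0592) or 2 (0.0565). Dcn and Cdh11 did not pass that test, with Dcn at 0.23 (adjusted p = 0.372) and Cdh11 at −0.28 (0.598). Other genes moved in opposite directions. Alcam, an adhesion molecule, fell by 1.96 in the human APE1 line and rose by 1.23 in the mouse Ape1 line, Ttc9 fell by 1.71 and rose by 1.59, and Ulbp1, a ligand of the receptor NKG2D, fell by 1.35 and rose by 1.56. Of 2287 genes that passed in both comparisons, 1962 (85.8%) moved the same way and 325 in opposite ways. Shared controls alone give a high share. Among genes at an unadjusted p under 0.05 in both comparisons, 82.7% of 4385 had the same sign. In 10 simulations of unchanged groups with shared simulated controls, 97.9% on average did (96.9% to 98.9%), but of only 259 genes on average (227 to 277). Without any effect, genes pass both tests mainly through the shared controls, so the simulated share is no baseline for the larger number observed. The observed share therefore neither shows a shared effect nor argues against one.

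Among transcript clusters, 1159 rose and 1288 fell in both lines, where independent lists would share 203 and 186, while 87 rose in the human APE1 line and fell in the mouse Ape1 line and 295 did the reverse, where independent lists would share 158 and 239. In 10 simulations of unchanged groups with shared simulated controls, limma called 0 transcript clusters in the same direction in both comparisons. That 0 follows from the lack of any effect in the simulations, and independent lists leave out the shared controls, so part of the overlap may come from those controls. Across transcript clusters, which are not independent replicates, the 2 effects correlated at r = 0.586. Unchanged groups with shared simulated controls gave 0.50 on average (0.482 to 0.526, 100 simulations). The covariance was 0.0797 against a simulated 0.0165, a difference of 0.0632. The simulations held only the spread between dishes, and each group was 1 line. A change of the vector control line alone could therefore give this difference, which does not show an effect shared by both proteins. With the 3 vector control arrays split between the comparisons, so that at least 1 comparison rests on a single control, r was 0.349 to 0.412 and the covariance 0.0555 to 0.0672. The split does not remove a change of the vector control line itself, which enters both effects. The signs of both effects were the same in 68.6% of transcript clusters, against 66.7% in the simulations.

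**Figure D3:**
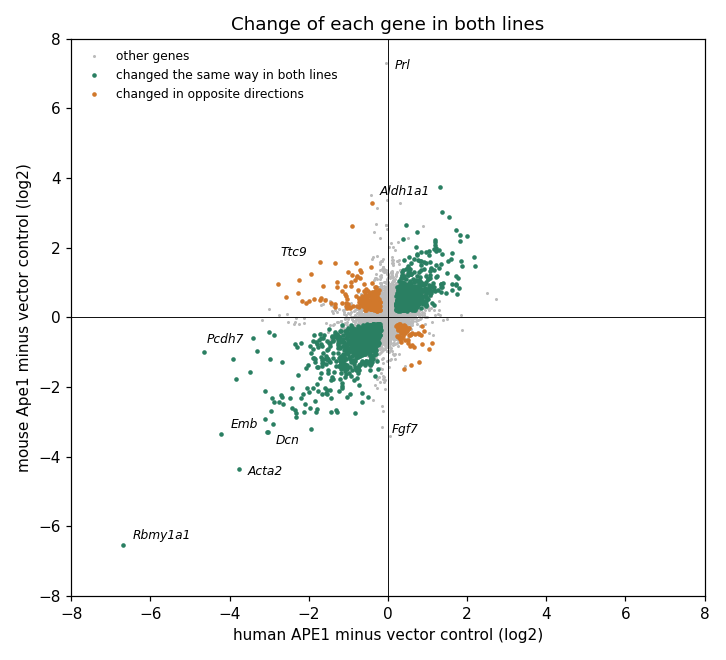
Log2 difference from vector control of 24647 genes in the human APE1 line (horizontal) and the mouse Ape1 line (vertical), coloured by whether a gene passed the test in both comparisons with the same sign (1962 genes) or with opposite signs (325 genes). Acta2 and Emb lie low on both axes, Prl lies high on the vertical axis alone, and Ttc9, which fell in one and rose in the other, lies left of and above 0.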

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

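The tests of chromosome medians, of the Y-linked genes and of the contractile genes were chosen after the results were seen.

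Single genes stood out because the change against vector control differed between the human APE1 and the mouse Ape1 line by the test of that difference itself, with opposite signs in the 2 lines. The difference, human APE1 minus mouse Ape1, was −3.30 for Ttc9 (adjusted p = 5.65e-05), −2.90 for Ulbp1 (2.18e-06), −3.19 for Alcam (1.88e-06), −3.31 for Ptprn (1.88e-06), −2.30 for Ildr2 (2.64e-05) and −2.29 for Ndst3 (1.15e-05), with all 3 arrays of the mouse Ape1 line above all 3 of the human APE1 line in each. These genes were chosen for large changes of opposite sign, so the separation and the passed test follow from the choice and add no support. Alcam had the same value (8.68) on all 3 vector control arrays, which lowers its estimated spread, so its adjusted p may be too small. Lists were flagged where the median had opposite signs in the 2 comparisons with vector control and camera with a preset correlation passed between the lines. The median difference was 0.21 for G2 and M phase genes (adjusted p = 1.41e-06), 0.18 for p53 targets (0.0385), 0.21 for cholesterol synthesis (0.00509) and −0.20 for the unfolded protein response (2.46e-05). The passed test follows from this choice and adds no support. Other lists with opposite medians, such as glycolysis and Hox genes, did not pass. Against vector control, the median was only 0.0087 for p53 targets in human APE1 and 0.0068 for the unfolded protein response in mouse Ape1. None of the 4 flagged lists passed with an estimated correlation, where adjusted p was 0.455 for the G2 and M phase genes and 0.601 for the other flagged lists. The p53 result was lost without vector control replicate 1 (adjusted p = 0.0560) and without human APE1 replicate 2 (0.0619) or 3 (0.121), when dim genes were left out of the background (0.0774) and after chromosome medians were subtracted (0.243).

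Many transcript clusters differed between the lines, 4859 for human APE1 against vector control, 6681 for mouse Ape1 against vector control and 5130 between human APE1 and mouse Ape1. Each pair of groups allows 10 splits of its 6 arrays, so a share under 0.05 is out of reach; the real split was the 1 with that many calls, and the highest other split gave 3, 0 and 0. For the 3-group test, 1 of 100 splits drawn from the possible ones, the real one, gave as many calls (8455, highest other 1419), which argues against chance in the grouping of the arrays.

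A candidate explanation for the number of calls is that the lines differ in their chromosome copies, as cultured fibroblast lines can. After the median of each chromosome was subtracted from each array, 5357, 6688 and 6407 transcript clusters passed in the 3 comparisons. Of these, 3777, 4957 and 3699 were among the 4859, 6681 and 5130 that had passed before, so many calls stayed once the shift of the whole chromosome was removed. For those calls, this argues against equal shifts of whole chromosomes as the whole cause. The other calls after subtraction were new, and changes of part of a chromosome were not removed. Copies that include such partial changes therefore stay open as the whole cause. As a part of the cause, copies stay open too. The chromosome accounted for an adjusted R squared of 0.0533, 0.0929 and 0.116 of the differences over 13189 expressed genes, between the bounds set for and against copies. Copies of chromosomes and other differences between the lines cannot be told apart here. The biological difference that the groups are named for, vector control, human APE1 or mouse Ape1, stays open as well and was not tested apart from the line.

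All 4 Y-linked genes were lower in the human APE1 line than in vector control, with differences from −0.75 for Eif2s3y to −1.15 for Ddx3y, and in each all 3 arrays of the human APE1 line lay below all 3 of vector control. Female cells mixed into the line are argued against by Xist, which differed by −0.12 (adjusted p = 0.789). Fewer copies of the Y chromosome may account for part of the fall, as the smallest fall of −0.75 allows. The falls were 0.39 apart (5.20 times the largest SE of a single gene's difference), and 25% of 8 expressed genes of the chromosome were higher. Whether equal copies give equal differences on these arrays was not tested, so the gap cannot decide whether copies alone account for the fall. Rbmy1a1, also Y-encoded, was lower in both lines (−6.68 and −6.54), though Ddx3y and Kdm5d rose in the mouse Ape1 line, so its fall did not follow theirs. Copies and regulation of these genes cannot be told apart without DNA, and an effect of human APE1 itself stays open, not tested apart from the line.

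The contractile genes Acta2 (−3.77 and −4.35 in the human APE1 and mouse Ape1 lines), Tagln (−2.19 and −2.31) and Actg2 (−2.10 and −2.49), the last chosen after its values were seen, were lower than in vector control in both lines. Cells of 1 of the 7 other types with marker lists in place of fibroblasts are argued against, because at most 8.33% of the markers of any 1 list rose in the human APE1 line and 8.33% in the mouse Ape1 line, while types with no list, such as those of the placenta or pituitary, were not tested. A candidate explanation is that the vector control line alone changed, which would leave the other lines alike. Of 130 genes at least 2-fold lower in both lines, 72 (55.4%) were not called different between human APE1 and mouse Ape1 and 58 were, so a change of the vector control line and an effect shared by human APE1 and mouse Ape1, the biological difference in the design, cannot be told apart.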

How the results depend on the processing

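The subtraction of chromosome medians was the only test of this part chosen after the data were seen; the cause of a change was not tested unless the alternative itself gives it. The 4 counts stayed within 1.5 times their value in 76 of 86 alternatives, and calls of named genes were the same in 7351 of 8072, lost in 714 and reversed in 7. Of 225 alternatives for list results that passed, 194 were the same and 31 lost, and of 1215 for those that did not pass, 34 gained. For human APE1 against vector control, mouse Ape1 against vector control, human APE1 against mouse Ape1 and all 3 groups, an adjusted p under 0.01, a stricter threshold, gave 2287, 3416, 2824 and 4707, and a change of at least 1.5-fold gave 1647, 2618 and 1958 in the comparisons of 2 groups. With each array left out in turn, which leaves fewer samples, the counts were 3185 to 4776 (3185 without human APE1 replicate 1, 3203 without human APE1 replicate 2), 4433 to 6772 (4433 without mouse Ape1 replicate 1), 3691 to 4892 and 6438 to 8243. The p-values of the authors' deposited table, adjusted in the same way, gave 4002, 5612, 4453 and 7115, of which 3344, 4789, 3770 and 6205 were shared. After quantile normalization was run again, 46.6%, 46.7% and 49.2% rose. Lists called were 0, 0 and 0 with an estimated correlation, whose allowance for correlated genes is wider, and 14, 17 and 14 with fry, which compares no list with other genes. Leaving out 1 array gave 6 to 7, 2 to 4 (4 without vector control replicate 2) and 3 to 6 (3 without human APE1 replicate 2), and dim genes left out of the background gave 3 for human APE1 against mouse Ape1. With fry, G1 and S phase genes passed in the other direction in human APE1 against vector control (adjusted p = 0.0134, lower). They also passed in mouse Ape1 against vector control (0.000533) and between human APE1 and mouse Ape1 (0.000106), as did glycolysis (0.00441 and 0.0153), and G2 and M phase genes passed in mouse Ape1 against vector control (0.00383). G2 and M phase genes had adjusted p = 0.463 and 0.455 with an estimated correlation in human APE1 against vector control and against mouse Ape1. Leave-one-out ranges of adjusted p in the 3 comparisons were 0.869 to 0.989, 0.405 to 0.592 and 0.638 to 0.733 for glycolysis, 0.874 to 0.974, 0.0568 to 0.134 and 0.0753 to 0.157 for G1 and S phase genes, and 0.00110 to 0.00741, 0.0647 to 0.174 and 8.92e-07 to 8.41e-06 for G2 and M phase genes. The correlation of both effects fell to 0.412, 0.360, 0.349, 0.398, 0.368 and 0.396 when the vector control arrays were split between the comparisons. The split removes the sharing of arrays but not of the vector control line, and also leaves fewer controls in each comparison (the parts were not separated). With 1 array left out, the correlation was 0.551 to 0.629. Chromosome medians subtracted turned the sign of Nsdhl (0.13) in human APE1 against vector control, of Tdp1 (−0.10) and Hsp90aa1 (−0.16) in mouse Ape1 against vector control, and of Apex2 (0.025), Cdk4 (−0.019), Nsdhl (0.086) and Hsp90aa1 (0.11) between human APE1 and mouse Ape1, and the cause was not tested beyond that construction. With the replicate number as a block the counts were 3747, 5569, 4162 and 6962 and the lists called 7, 2 and 6, and arrays of the same number correlated in their deviations at r = −0.0750 to 0.104 (9 pairs), those of other numbers at −0.118 to 0.118 (18 pairs), which does not show that the numbers pair the dishes, and 3 of 9 arrays correlated best with an array of their own number. The number of arrays limits the detection of small changes, of which 2% at 1.2-fold were recovered in simulated data. Far fewer transcript clusters were changed there than were called in human APE1 against vector control, so recovery in the real data may differ.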

Other observations

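The families of transcripts and the chromosomes described here were chosen after their values were seen. Chromosome copies were weighed among the results flagged above, and no other test of an explanation was run for this part.

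Beside prolactin itself, other members of its family were higher in the mouse Ape1 line. The array held 26 transcript clusters for 24 genes of the prolactin family, of which 5 rose against vector control in that line. They were Prl (7.32), Prl3d3 on 2 clusters (2.59 and 1.40), Prl7a2 (1.28) and Prl3d1 (1.16), of which all but Prl are known from the placenta, and which member was measured is uncertain because the copies are alike in sequence. The vector control means of Prl (4.25) and Prl7a2 (3.26) lay below the 25th percentile of those arrays (4.27 to 4.32), so the size of these rises is uncertain. In the human APE1 line the whole family lay between −0.17 and 0.38 on the log2 scale. In the authors' deposited table, the ratio of vector control over human APE1 for Prl was 1.12 (p = 0.363). Rbmy1a1 stood on 9 transcript clusters, all lower than in vector control, with differences of −6.68 to −6.38 in the human APE1 line and −6.54 to −6.06 in the mouse Ape1 line. The authors' deposited table gives ratios of vector control over human APE1 and over mouse Ape1 of 83.8 (p = 3.67e-09) and 66.5 (p = 5.07e-09) for Rbmy1a1. The means of all Rbmy1a1 clusters in both lines lay below the 25th percentile of their arrays, so the size of these falls and ratios is uncertain.

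Expressed genes of some chromosomes moved together. On chromosome 12, 75.2% of 479 genes were higher in the mouse Ape1 line than in vector control, with a median difference of 0.36, and the median between human APE1 and mouse Ape1 was −0.24. On chromosome X (424 genes) the median was −0.18 for human APE1 against vector control, 0.11 for mouse Ape1 against vector control and −0.29 between human APE1 and mouse Ape1. On chromosome 10, 83.4% of genes were higher in the human APE1 line than in the mouse Ape1 line, with a median of 0.22. Chromosome 15 had a median of −0.17 in the mouse Ape1 line and chromosome 18 one of −0.16 in the human APE1 line, both against vector control. Among genes at least 2-fold higher than in vector control in both lines there were 41, of which 24 differed between human APE1 and mouse Ape1 and 17 did not pass that test.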
